A study of Mus musculus with 12 samples.

How the data were processed

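RNA was measured by sequencing of poly(A)-selected mRNA in MPC5 cells, an immortalized mouse podocyte line. Podocytes are the epithelial cells that cover the outer face of the glomerular capillaries. Per the labels' protocols, cells received either an empty plasmid (the vector group, 6 libraries) or a plasmid for overexpression of Sparc (the SPARCoe group, 6 libraries). They were profiled 24 hours after transfection. RNA was extracted with TRIzol, mRNA was selected with polyT and fragmented, and libraries were amplified by PCR. The labels do not say that the 6 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

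The authors deposited a table of read counts per Ensembl gene and a table of FPKM values for the same genes and libraries. Bowtie2, HISAT2, featureCounts, SAMtools, Picard and edgeR are named in the submitters' processing notes, without a version, role or order. The genome build, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. The deposited counts were whole numbers for 55487 genes and were used without change. Each deposited FPKM value equalled the count divided by the library's total count and by 1 length per gene. For all 31742 genes with a value, that length came out whole (within 0.001) and the same in every library. It equalled the merged exon length in GENCODE M21 for 45.71% of 31635 genes, so positions from M21 (GRCm38) are named as such and are not the authors' coordinates. Among deposited counts of 1 or 2, 56.67% were 2, and 56.36% of counts from 1 to 10 were even. Read pairs thus appear to add 2 counts in many cases, reads carry no molecular identifiers, and intervals and floors cover counting error only and are too narrow.

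Gene symbols were taken from a reference table and matched 55141 of the 55487 IDs. IDs without a symbol held between 0.0316% and 0.0476% of the counts of a library. Library totals ran from 33051035 to 47380987 counts. A floor of 3 counts corresponds to 0.0633 to 0.0908 CPM (counts scaled to the library's total) in single libraries. Genes with near-identical copies, such as the Oas1, Ifit3, Saa and H2 families, may have split or shared reads. Reads of a gene and an antisense or overlapping partner cannot be told apart without a stated strand setting.

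The main test was edgeR 4.0.16 in R 4.3.3: TMM factors, genes kept by filterByExpr (15734 genes), a robust quasi-likelihood fit (glmQLFit, glmQLFTest) of SPARCoe against vector on all 12 libraries, and a two-sided Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values used the TMM factors, and log2 CPM used a prior count of 2. Gene lists were tested with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01, two-sided. Adjustment covered the 24 of 25 lists that had at least 5 tested members. Beside each count of members past the adjusted p over all genes, a count adjusted over the list alone was made. Sparc was also tested by an exact permutation test of log2 CPM over all 924 assignments of the 12 libraries to groups of 6.

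The lists, tests and alternatives were fixed before the data were examined, and so was the rule for the genes named. The rule took Sparc, then the 10 largest rises and the 10 largest falls. Those were genes past the adjusted p with a mean of at least 1 CPM in the higher group and at least 5 of 6 SPARCoe libraries on the called side of the vector median. Predicted genes, Rik genes, pseudogenes and IDs without a symbol were counted but not named. From each list it took up to 4 passing members with the smallest adjusted p, or the 2 most abundant members when none passed. Nphs1, Synpo, Podxl, Wt1 and Col4a1 to Col4a5 were always given. Some genes that the rule took are not reported here. Other genes named were chosen after their values were seen, and are said to be so.

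Alternatives were RLE and upper-quartile factors, Sparc left out of library sizes and fit, no filter on low counts, and a filter of at least 1 CPM in at least 6 libraries. Further tests were DESeq2 1.42.0 with its Wald test, limma-voom with sample quality weights, a replicate block, 1 surrogate variable from svaseq (sva 3.50.0), glmTreat against a 1.2-fold change and an adjusted p under 0.01. The deposited FPKM values were tested with limma trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean of at least 1 FPKM, and on log2(FPKM + 1) for all genes with a value. Each of the 12 libraries was left out in turn. Lists were also tested with an estimated correlation and with fry. Offsets for GC content and gene length (a lowess smooth with a span of 0.3, available for 99.89% of the tested genes) were added after the data were seen.

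The pipeline was tested on simulated data: counts drawn for the real genes from the real means, library sizes and dispersions, with 200 genes changed. For the simulated SPARCoe against vector comparison, edgeR tested 15549 genes. It recovered 32 of 48 genes changed 1.3-fold, 40 of 48 changed 1.5-fold, 43 of 49 changed 2-fold and 48 of 48 changed 4-fold. No recovered gene had the wrong sign, and 10 unchanged genes were called, which was 5.78% of the calls. The simulated changes went up and down equally and were at most 4-fold, while 520 of 535 real changes of 2-fold or more were rises. The simulation thus does not check scaling or false calls under many and uneven changes. On 200 simulated lists without a change, camera with the preset correlation gave a p under 0.05 for 9 lists. Genes were drawn independently there, so the simulation does not check the test on lists with correlated members. In the real data the estimated correlation was 0.255 for the interferon response list.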

Results

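SPARC (secreted protein acidic and rich in cysteine, or osteonectin) is a matricellular protein that binds collagen. The series concerns its part in podocyte injury in Alport syndrome, a hereditary kidney disease caused by mutations of the collagen IV chains of the glomerular basement membrane. The data are 12 mRNA-seq libraries of the mouse podocyte line MPC5, 6 from cells that received an empty vector and 6 from cells that received a Sparc overexpression plasmid (SPARCoe), all 24 hours after transfection. Total counts ran from 33051035 to 47296258 in the vector libraries and from 34927871 to 47380987 in the SPARCoe libraries. The 10 most abundant genes held 4.06% ± 0.02 of the counts in vector and 4.72% ± 0.08 in SPARCoe (SD, n = 6). Mitochondrial transcripts held 1.24% to 1.43% in vector and 1.22% to 1.35% in SPARCoe. More genes had at least 1 count in SPARCoe (23581 ± 494.7) than in vector (21797 ± 216.2; SD, n = 6), at similar depth.

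Sparc was 13.5-fold higher in the SPARCoe libraries. Its level was 751 ± 11.2 CPM in vector and 10119.7 ± 260.5 CPM in SPARCoe (SD, n = 6), a log2 fold change of 3.75 ± 0.02 (SE, edgeR adjusted p = 6.69e-61). Single vector libraries lay between 740.9 and 772.1 CPM and single SPARCoe libraries between 9751.4 and 10523.5 CPM. An exact two-sided permutation test of log2 CPM gave p = 0.00216 for 6 against 6 libraries, the smallest value these groups allow. In SPARCoe, 1.01% ± 0.02 of all counts fell on Sparc, against 0.0751% ± 0.0013 in vector (SD, n = 6). Sparc (ENSMUSG00000018593) lies on chromosome 11 from 55394500 to 55423183 on the minus strand in GENCODE M21 (GRCm38), with no overlapping gene in that annotation. Counts per gene do not separate plasmid-derived from chromosomal Sparc transcripts.

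**Figure D1:**
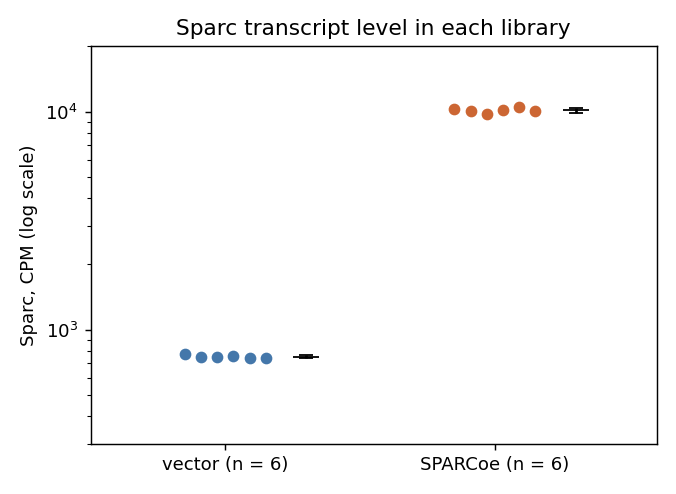
Sparc level in CPM (log axis) in each of the 6 vector and 6 SPARCoe libraries, with the mean and SD of each group as black bars. Vector libraries lie between 740.9 and 772.1 CPM and SPARCoe libraries between 9751.4 and 10523.5 CPM.

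The comparison of SPARCoe with vector asks which other transcripts differ when MPC5 cells carry the Sparc plasmid. The interferon response, NF-kB and inflammation, and immediate early gene lists were higher, while the basement membrane, adhesion, actin cytoskeleton and tubule lists were lower, most members by small amounts. Of 15734 genes tested, 4571 changed (edgeR adjusted p under 0.05), 2347 upward and 2224 downward. The balance of directions depended on the setting, with 1669 rises and 2059 falls by limma on log2(FPKM + 1) for genes with a mean of at least 1 FPKM, 2294 and 1600 over all FPKM genes, and 854 and 138 by glmTreat against 1.2-fold. Most changes were small: 60.95% of the changed genes differed by less than 1.2-fold. Changes of 2-fold or more numbered 535, of which 520 were rises and 15 were falls. Among the 520 rises, 343 had a mean under 1 CPM, and at a mean of 100 CPM or more there were 6 rises and 0 falls of that size. By DESeq2, 1107 genes changed 2-fold or more, 1079 of them upward, and with a filter of at least 1 CPM in at least 6 libraries edgeR gave 206, of which 200 were rises. The number was 1432 with no filter on low counts and between 67 and 110 on the deposited FPKM values.

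Libraries separated by group. The first principal component of log2 CPM held 45.2% of the variance and placed all vector libraries at -26.01 or below and all SPARCoe libraries at 26.97 or above. Pearson correlations of log2 CPM across genes were 0.9911 to 0.9939 within groups and 0.9827 to 0.986 between groups. The second component (7.34% of the variance) set vector replicate 4, the library with the lowest total count, apart from the rest. The 30 pairs of libraries within a group differed, with a chi-square per degree of freedom of 4 to 7.93. Independent counts would give 1 and read pairs counted as 2 would give 2, and the measure covers counting error only.

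**Figure D2:**
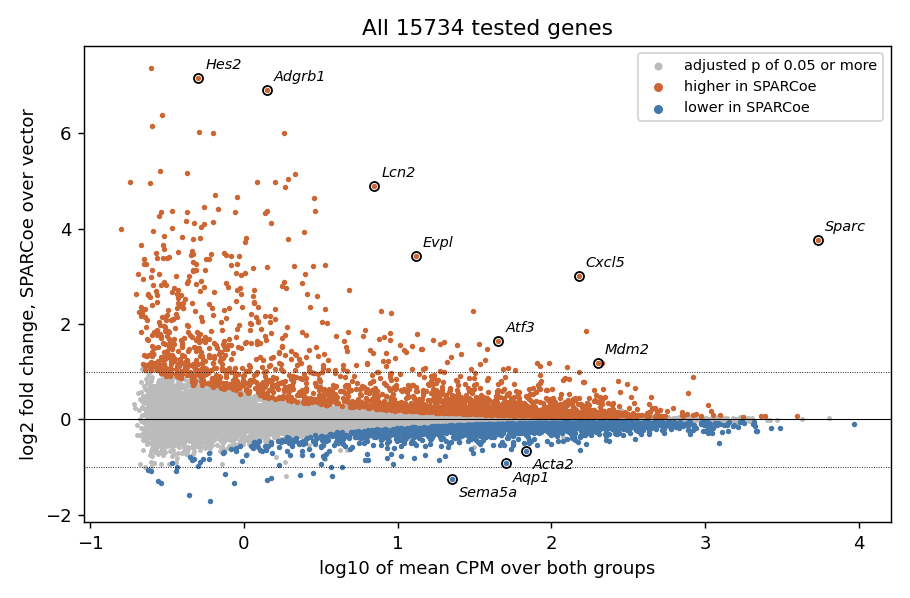
Log2 fold change of SPARCoe over vector against the log10 of the mean CPM over both groups, 1 point per tested gene, with genes past the adjusted p in orange (higher) or blue (lower) and dotted lines at 2-fold. Of the 2-fold changes, 520 lie above and 15 below the lines.

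The largest rises were in genes that were nearly silent in vector libraries. Hes2, a transcription factor of the Hairy and Enhancer of split family, had 1 count in the 6 vector libraries together and 256 in SPARCoe, a ratio of 246.7 with a 95% counting interval of 43.88 to 9781. Sncaip, which encodes the synuclein-interacting protein synphilin, had 3 and 254 counts, a ratio of 81.59 (27.6 to 398.3). Adgrb1, an adhesion G protein-coupled receptor, rose from 0.0196 ± 0.0232 to 2.80 ± 0.264 CPM (SD, n = 6). The cyclic nucleotide-gated channel gene Cnga3 had 4 and 316 counts, a ratio of 76.13 (29.44 to 281.1), and the exocyst-like gene Exoc3l2 27 and 960, a ratio of 34.26 (23.4 to 52.27). Trp73, a transcription factor of the p53 family, rose from 0.0974 ± 0.0858 to 3.08 ± 0.652 CPM, and the epithelial transcription factor gene Grhl3 from 0.0667 ± 0.0954 to 2.38 ± 0.543 CPM (SD, n = 6). In the annotation used here Trp73 overlaps the antisense gene Trp73os, so its reads may include that transcript. Saa3 (serum amyloid A), Nos2 (inducible nitric oxide synthase) and Lcn2 (lipocalin) completed the 10, with count ratios of 66.94 (38.94 to 126.2), 36.48 (25.09 to 55.17) and 30.11 (24.9 to 36.74). All 10 passed the edgeR test with adjusted p of 1e-11 or less, and all 6 SPARCoe libraries lay above the vector median for each.

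The largest falls were about 2-fold, and most were in genes of low level. Sema5a, a semaphorin, was the most abundant of them and fell from 31.7 ± 2.37 to 13.2 ± 0.95 CPM (SD, n = 6; log2 fold change -1.26 ± 0.05, edgeR adjusted p = 7.18e-23). Slc24a3, a sodium/calcium exchanger gene, fell from 5.17 ± 0.794 to 2.27 ± 0.291 CPM. Myl9, a myosin light chain of smooth muscle, fell from 5.83 ± 0.716 to 2.92 ± 0.566 CPM, and Angpt4 from 4.89 ± 0.678 to 2.46 ± 0.143 CPM (SD, n = 6). The other 6 were Upk3b (log2 fold change -1.33 ± 0.23), Map3k21 (-1.27 ± 0.20), Ms4a2 (-1.22 ± 0.20), Sox8 (-1.16 ± 0.16), ccdc198 (-1.12 ± 0.15) and Slco1a6 (-0.95 ± 0.16).

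Interferon response genes rose almost without exception. Of 44 tested members, 43 rose and 0 fell (44 and 0 adjusted over the list alone), with a median log2 fold change of 0.84. Irf7, a transcription factor that drives type I interferon expression, rose from 86.4 ± 2.58 to 157.7 ± 3.42 CPM, and the guanylate-binding protein gene Gbp3 from 49.4 ± 3.23 to 111.8 ± 3.12 CPM (SD, n = 6). Ifi44 rose 2.98-fold and Oasl2, of the oligoadenylate synthetase family, 1.98-fold. The list was higher in SPARCoe by camera (adjusted p = 5.34e-42; adjusted p = 0.0177 with an estimated correlation). Leukocyte markers did not move with it: 1 of 5 tested members rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 0.888), Csf1r falling from 8.30 ± 0.833 to 4.58 ± 0.504 CPM and Cd14 rising from 5.83 ± 0.586 to 8.83 ± 0.917 CPM (SD, n = 6). The median of that list was 0.19 and its mean -0.04 on the log2 scale.

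NF-kB and inflammation genes also rose as a group, with 23 of 35 tested members higher and 3 lower (24 and 3 adjusted over the list alone). The neutrophil chemokine gene Cxcl5 rose 8.01-fold, from 33.4 ± 1.89 to 267.2 ± 8.86 CPM (SD, n = 6; edgeR adjusted p = 9.03e-46). Ptgs2, which encodes cyclooxygenase 2, rose 2.13-fold, the monocyte chemokine gene Ccl7 rose from 9.37 ± 0.834 to 28.2 ± 2.49 CPM, and Lcn2 from 0.457 ± 0.149 to 13.6 ± 2.41 CPM (SD, n = 6). The 3 that fell were Traf1, Relb and Nfkb2 (log2 fold change -0.40, -0.17 and -0.07), chosen after their values were seen. The camera adjusted p was 1.45e-12 (adjusted p = 0.0303 with an estimated correlation).

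Immediate early genes were higher as well. Of 28 tested members, 20 rose and 2 fell (21 and 3 adjusted over the list alone). The stress-induced transcription factor gene Atf3 rose from 21.8 ± 1.48 to 68.3 ± 1.59 CPM (SD, n = 6), Klf4 1.79-fold, Ier3 1.44-fold and Jun, an AP-1 subunit, 1.35-fold. The camera adjusted p was 2.11e-09 (adjusted p = 0.042 with an estimated correlation).

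Basement membrane genes were lower, by less than 1.4-fold for the named members. Of 20 tested members, 13 fell and 1 rose (15 and 1 adjusted over the list alone). Col4a1 and Col4a2, neighbours on chromosome 8 that encode the collagen IV chains found in most basement membranes, fell from 460.3 ± 10.6 to 399.3 ± 8.68 CPM and from 385.1 ± 4.29 to 334.5 ± 2.99 CPM (SD, n = 6). Of the chains mutated in Alport syndrome, Col4a5 on chromosome X fell from 325.4 ± 5.65 to 258.4 ± 7.12 CPM (log2 fold change -0.33 ± 0.02, edgeR adjusted p = 2.4e-17). Col4a4 on chromosome 1 fell from 5.03 ± 0.86 to 3.64 ± 0.357 CPM (SD, n = 6; edgeR adjusted p = 0.00085), and did not pass by limma on log2(FPKM + 1) over all genes (adjusted p = 0.0579). Its partner Col4a3, with 508 counts in vector and 390 in SPARCoe, had a log2 fold change of -0.44 ± 0.19 and did not pass (edgeR adjusted p = 0.0739). Without vector replicate 4 or without SPARCoe replicate 5 it passed (edgeR adjusted p = 0.0184 and 0.0348). Lamb2, the laminin chain of the mature glomerular basement membrane, fell by 0.22 on the log2 scale. The member that rose was Lama1 (log2 fold change 0.89 ± 0.18, SE), named after its value was seen. The list was lower by camera (adjusted p = 1.19e-05; adjusted p = 0.0409 with an estimated correlation).

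**Figure D3:**
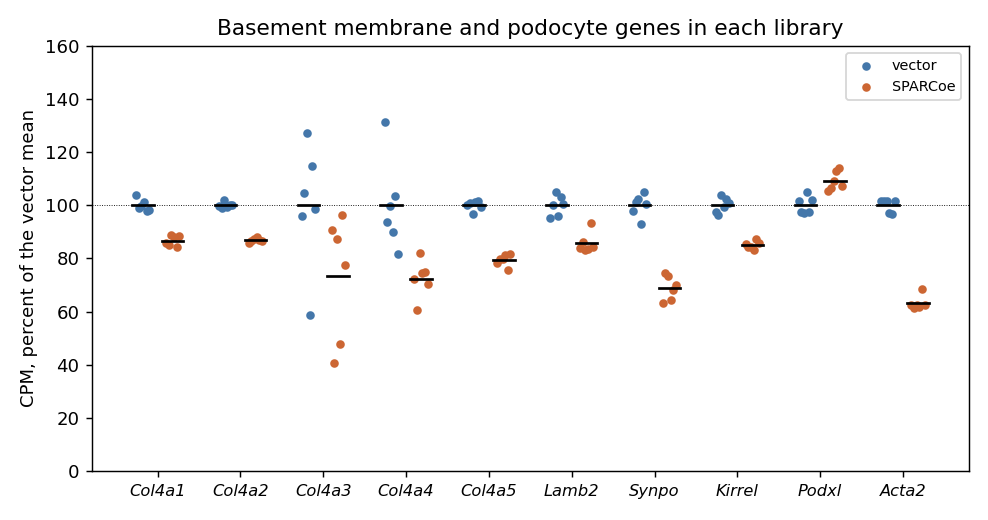
CPM of 10 genes in each library as a percent of the gene's mean in vector, with vector libraries in blue, SPARCoe libraries in orange and group means as black bars (n = 6 per group). Col4a1, Col4a2 and Col4a5 show tight and separate groups, while the scarce Col4a3 and Col4a4 scatter more.

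Podocyte markers moved in both directions. Of 20 tested members, 8 fell and 3 rose (9 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0984; adjusted p = 0.257 with an estimated correlation). Synpo, the actin-associated protein of podocyte foot processes, fell from 66.6 ± 2.79 to 45.99 ± 3.06 CPM (SD, n = 6; edgeR adjusted p = 8.85e-16). Kirrel, which encodes the slit diaphragm protein NEPH1, fell by 0.23 and the intermediate filament gene Nes by 0.19 on the log2 scale. Podxl, the major sialoglycoprotein of the podocyte surface, rose by 0.13 ± 0.03 and Vegfa by 0.38 ± 0.04 (log2, SE). Nphs1, which encodes the slit diaphragm protein nephrin, was close to silent and too low for the test. It had 0 counts in all 6 vector libraries and 3 to 14 per SPARCoe library, 53 in all, which is at least 17.02-fold higher with a floor of 3 counts over the group (exact two-sided permutation p = 0.00216, adjusted p = 0.00649 over 3 genes). Wt1, a podocyte transcription factor gene, had 37 and 20 counts in all, a ratio of 0.521 (0.286 to 0.921, exact permutation p = 0.0714). Nphs1 and Wt1 were thus scarce in vector, where the tubule markers Lrp2 and Pax8 were at 257.9 and 155.8 CPM. The results describe MPC5 cells and may not carry over to podocytes in the kidney.

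Genes of cell adhesion and the cytoskeleton were lower as groups. Abundant genes leaned the same way: of 2503 tested genes at a mean of 100 CPM or more, 755 fell and 398 rose. Camera set each list against all other tested genes, not against genes of like level. A lean shared with abundant genes was thus not separated, here or for the basement membrane list. For integrins and focal adhesion, 11 of 28 tested members fell and 3 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.00908, and adjusted p = 0.0409 with an estimated correlation). Tns1 (tensin), which links integrins to actin, fell from 186.3 ± 7.31 to 118.6 ± 6.11 CPM (SD, n = 6), while Dag1 (dystroglycan), Tln1 (talin) and Vcl (vinculin) fell by 0.29, 0.18 and 0.18 on the log2 scale. For the actin cytoskeleton, 15 of 30 tested members fell and 2 rose (16 and 3 adjusted over the list alone; camera adjusted p = 0.00383, and adjusted p = 0.042 with an estimated correlation). Myh9, the non-muscle myosin heavy chain of podocytes, fell from 2369 ± 33.9 to 2009 ± 40.5 CPM (SD, n = 6), Cald1 (caldesmon) and Flna (filamin A) fell by 0.24 and 0.18 on the log2 scale. Synpo2 went the other way and rose 4.72-fold, from 3.16 ± 0.27 to 14.9 ± 0.839 CPM (SD, n = 6). The mean of the actin list was 0.01 and its median -0.07.

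Interstitial matrix genes split, with 11 of 28 lower and 6 higher (the same counts adjusted over the list alone; camera adjusted p = 0.274, and adjusted p = 0.404 with an estimated correlation). With a filter of at least 1 CPM in at least 6 libraries the list passed (camera adjusted p = 0.0196). Col5a2 fell by 0.26, Thbs1 by 0.23 and Col6a1 by 0.34 on the log2 scale. Thbs2, a thrombospondin, rose from 0.02 ± 0.0233 to 0.837 ± 0.18 CPM (SD, n = 6), and the list had a mean of 0.20 beside a median of -0.04. Matrix remodelling enzymes split likewise, with 11 of 31 lower and 8 higher (13 and 10 adjusted over the list alone; camera adjusted p = 0.364). Among enzymes that hydroxylate or cross-link collagen, P4ha1, Loxl1 and Loxl2 fell by 0.31, 0.34 and 0.36 on the log2 scale, and Lox rose from 11.7 ± 0.709 to 19.6 ± 0.743 CPM (SD, n = 6). The mean of that list was 0.05 and its median -0.02. TGF-beta and myofibroblast genes had 9 of 36 lower and 11 higher (12 and 11 adjusted over the list alone; camera adjusted p = 0.349). Acta2, smooth muscle actin, fell from 83.7 ± 2.02 to 52.8 ± 2.23 CPM and the TGF-beta co-receptor gene Tgfbr3 rose from 58.6 ± 2.96 to 93.0 ± 5.46 CPM (SD, n = 6). The actin-binding genes Cnn2 and Tpm1 fell by 0.31 and 0.28 on the log2 scale. Of the SPARC family only Sparc and 1 other member were tested, too few for a list test, and only Sparc rose (1 and 0 adjusted over the list alone).

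Some p53-regulated and apoptosis genes rose more than 2-fold. Mdm2, the ubiquitin ligase that restrains p53, rose from 122.6 ± 4.62 to 277.0 ± 5.42 CPM (SD, n = 6; edgeR adjusted p = 3.73e-35). Bbc3 (PUMA), Fas and Trp53inp1 rose 2.46-fold, 2.43-fold and 2.12-fold. Over the list, 12 of 28 tested members rose, 6 fell and 10 did not pass (14 rises and 7 falls adjusted over the list alone). Among other p53 targets, named after their values were seen, Cdkn1a rose only 1.10-fold. Bax, Ccng1 and Phlda3 did not pass (edgeR adjusted p = 0.126, 0.0861 and 0.773). The camera adjusted p was 0.00397, and the call was lost with an estimated correlation (adjusted p = 0.179 with an estimated correlation).

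Of 30 G2 and mitosis genes, 11 fell and 1 rose (13 and 1 adjusted over the list alone). The camera adjusted p was 0.00387, and the call was lost with an estimated correlation (adjusted p = 0.247 with an estimated correlation). Mki67, a proliferation marker, fell from 684.3 ± 21.2 to 612.9 ± 10.4 CPM (SD, n = 6), and Nusap1, Dlgap5 and Ube2c fell by 0.23, 0.17 and 0.14 on the log2 scale. Of 30 S phase genes, 6 fell and 4 rose (6 and 5 adjusted over the list alone; camera adjusted p = 0.552). Pole fell by 0.14 and Prim1 by 0.12, while E2f2 and Cdt1 rose by 0.24 and 0.12 on the log2 scale.

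Hypoxia and glycolysis genes had 11 of 26 higher and 1 lower (12 and 1 adjusted over the list alone). The camera adjusted p was 0.00649, and the call was lost with an estimated correlation (adjusted p = 0.257 with an estimated correlation). Hk2 (hexokinase), Ddit4 and Vegfa rose by 0.38, 0.36 and 0.38 on the log2 scale, and P4ha1 was the member that fell (-0.31).

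The remaining stress and metabolism lists did not pass the list test. Of 28 unfolded protein response genes, 7 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.746), among them Sesn2 (log2 fold change 0.47 ± 0.04, SE), Ppp1r15a (0.33 ± 0.04), Psat1 (0.15 ± 0.02) and Atf4 (-0.26 ± 0.02). The median of that list was -0.01 and its mean 0.04. Of 21 NRF2 response genes, 7 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.632), with Hmox1 and Fth1 higher by 0.42 and 0.18 and Gstm1 and Gclc lower (-0.54 and -0.27); its median was 0.04 and its mean -0.03. Of 19 heat shock genes, 7 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.274), with Hsph1 and Dnajb1 higher by 0.20 and 0.17 and Dnajb4 and Cryab lower (-0.28 and -0.19). Of 24 cholesterol synthesis genes, 7 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 0.0722). Without vector replicate 1 or without SPARCoe replicate 5 the list passed (camera adjusted p = 0.0303 and 0.0146), as it did with the filter of at least 1 CPM (0.0267), while with an estimated correlation on all libraries it did not (adjusted p = 0.442 with an estimated correlation). Insig1, Sc5d and Hsd17b7 rose by 0.21, 0.25 and 0.13 on the log2 scale. The 14 tested mitochondrial transcripts had edgeR adjusted p of 0.194 or more, and none passed adjusted over the list alone (camera adjusted p = 0.552). Its most abundant members, mt-Co1 and mt-Nd1, were at 6315 ± 325 and 1742 ± 101 CPM in vector and 6404 ± 141 and 1748 ± 71.5 CPM in SPARCoe (SD, n = 6). Of 30 ribosomal protein genes, 4 fell and 0 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.308): Rpl6, Rpl4, Rpl11 and Rpl10, each by 0.06 on the log2 scale. With upper-quartile factors Rpl11 and Rpl10 did not pass (edgeR adjusted p = 0.0614 and 0.0857). Rpl10 did not pass by DESeq2 either (Wald test adjusted p = 0.0708), and both lost the call in several fits with 1 library left out.

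Among markers of other kidney cell types, tubule markers were lower. Of 10 tested members, 7 fell and 1 rose (the same counts adjusted over the list alone; camera adjusted p = 4.16e-05, and adjusted p = 0.0308 with an estimated correlation). The member that rose was Slc12a3, with 13 counts in vector and 111 in SPARCoe, named after its value was seen, and the list had a median of -0.28 beside a mean of -0.02 on the log2 scale. The water channel gene Aqp1 fell from 66.1 ± 4.36 to 34.8 ± 1.97 CPM, the endocytic receptor gene Lrp2 (megalin) from 257.9 ± 1.56 to 192.6 ± 5.79 CPM, and the nephron transcription factor gene Pax8 from 155.8 ± 4.62 to 128.0 ± 1.73 CPM (SD, n = 6). Of 13 mesangial and fibroblast markers, 5 fell and 2 rose (the same counts adjusted over the list alone; camera adjusted p = 0.138, and 0.0114 with the filter of at least 1 CPM), with Acta2, Postn and Pdgfrb lower (-0.66, -0.85 and -0.40) and Notch3 higher by 0.74 on the log2 scale; the median was -0.18 and the mean 0.00. Of 10 endothelial markers, 3 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.746). Flt1 fell from 41.3 ± 1.6 to 30.4 ± 1.59 CPM, and Eng, Robo4 and Tek rose from 1.22 ± 0.334, 0.121 ± 0.0917 and 0.160 ± 0.168 CPM to 3.13 ± 0.6, 0.933 ± 0.341 and 0.514 ± 0.137 CPM (SD, n = 6).

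**Figure D4:**
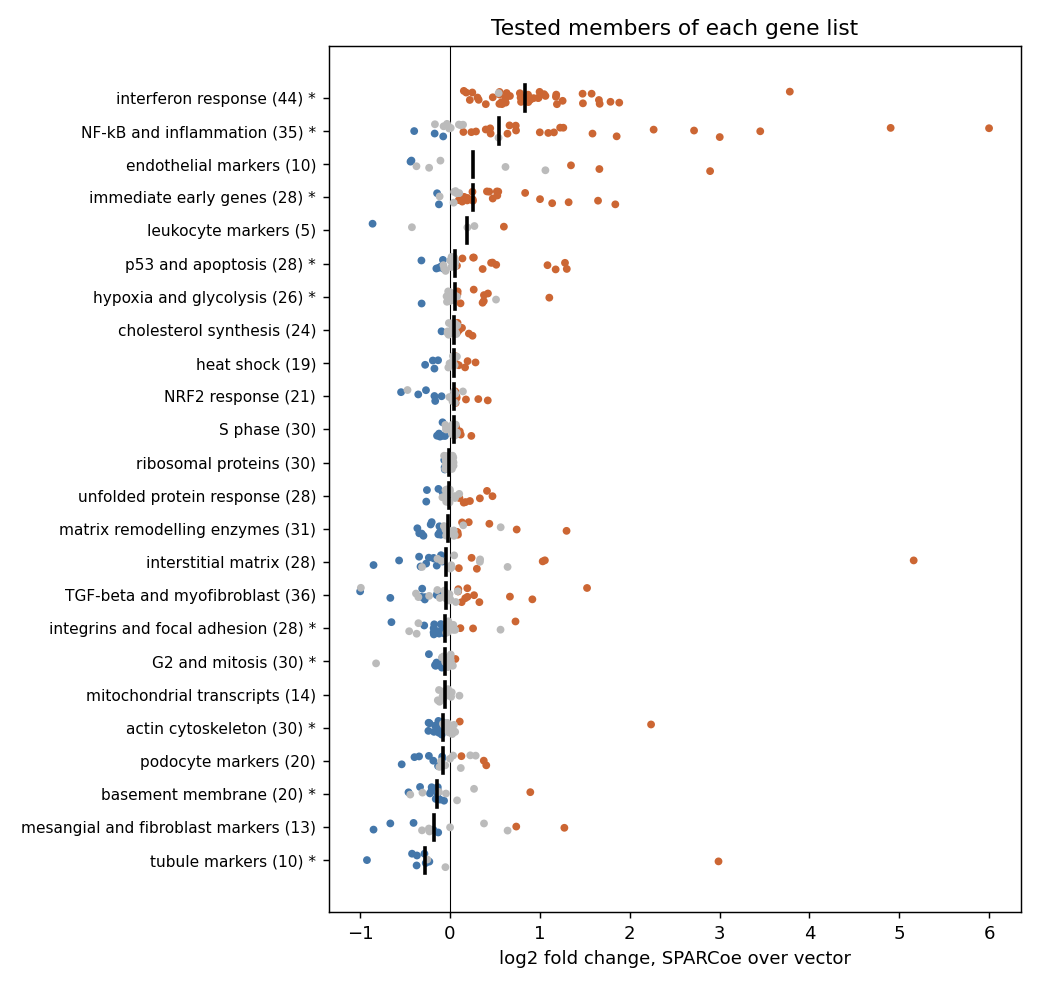
Log2 fold change of SPARCoe over vector for the tested members of the 24 lists, with the number of members in parentheses, members past the adjusted p in orange (higher) or blue (lower), others in grey, and the list median as a black bar. Asterisks mark the 10 lists with a camera adjusted p under 0.05 at the preset correlation, of which 7 passed with an estimated correlation.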

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

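The tests of leukocytes and of plasmid DNA on the interferon genes, and the tests of Trp53 reads and of the p53 list, were chosen after the results were seen.

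Interferon response genes were higher in SPARCoe, 43 of 44 tested members by edgeR. Leukocytes mixed into the cultures are argued against: all 18 leukocyte markers together summed to 20.8 CPM in vector and 21.2 CPM in SPARCoe, and the SPARCoe sum is 1.21% of the summed rise of the interferon list (1753 CPM; 1.17% to 1.29% over the SPARCoe libraries). A response to plasmid DNA that differed in amount or kind between the groups cannot be told apart from an effect of SPARC protein, because plasmid and group coincide and Sparc CPM varied by a CV of only 2.57% within SPARCoe. Both therefore stay open, and the design has no group that would separate them.

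Changes of 2-fold or more were rises in 520 of 535 genes. Genomic DNA in the SPARCoe libraries is argued against as the main source of these rises. Per kb, 1481 chemosensory receptor genes gained 0.474% of the median gain of the 343 low-abundance rises (0.372% to 0.545% over the SPARCoe libraries). Those receptor genes did rise, with 2834 counts in vector and 3813 in SPARCoe, a CPM ratio of 1.3. Read-through from a higher gene upstream may account for part. On the same strand, 8.08% of the rises (42 of 520, 95% interval 5.88% to 10.8%) had such a neighbour ending within 10 kb. Of 519 matched unchanged genes, 1.73% did (Fisher exact p = 1.97e-06). Most rises thus had no such neighbour. Read-through from farther upstream, from overlapping genes or from the opposite strand was not counted. Its whole share therefore stays unknown. With offsets for GC content and gene length, 97.22% of the 2-fold changes were rises, which argues against those biases as the whole cause. A response of the cells to the Sparc plasmid stays open as a hypothesis.

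Trp73 and some p53 targets, such as Mdm2, rose in SPARCoe. Reads of Trp53 assigned to Trp73 are argued against, as Trp53 had a log2 fold change of 0.00466 (313 ± 15.5 and 314 ± 6.91 CPM; SD, n = 6). By camera the p53 and apoptosis list was higher (adjusted p = 0.00397), but not with an estimated correlation (camera adjusted p = 0.179). Its members did not all rise, with 12 called higher and 6 lower. The 6 were Gdf15 (log2 fold change -0.32), Casp8 (-0.15), Zmat3 (-0.12), Tnfrsf10b (-0.10), Bcl2l1 (-0.08) and Mcl1 (-0.07). These counts were already known, so they describe the list and are no independent test. A response of part of the targets, through Trp73 or otherwise, stays open and was not tested.

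Other splits of the 12 libraries into 6 and 6 bear on the counts themselves. Of 100 splits, 1 gave at least 4571 changed genes, the real one, and the highest other gave 14. For 2-fold changes, 1 of 100 gave at least 535, again the real one, and the highest other gave 3. For gene lists, 3 of 100 splits, the real one included, gave at least 10 lists, the highest other gave 10 and the median of the others was 3. For the gene counts, a chance assignment of these 12 libraries to groups can be excluded. A difference between cultures that has nothing to do with Sparc cannot. The labels do not say that the libraries of a group came from separate cultures. Although 3 of 100 is under 1 in 20, 2 other splits reached the real number of lists, so that number is less secure.

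Single libraries lay apart from the other 5 of their group in 17 of 231 sets of values, by the gap to the nearest library over the range of the group. Chance gives about 1 in 20, or 11.6 sets. In vector replicate 1, Thbs1 (1480 CPM against 1528 to 1554) and Psat1 (644.8 against 675.2 to 678) were low and Cxcl5 was high (37.02 against 31.8 to 33.6). In vector replicate 2, Nos2 was high (0.329 against 0.0426 to 0.128). In vector replicate 3, Slco1a6 was low (1.805 against 2.21 to 2.40), and Col4a2 (393.2 against 381 to 385.1) and Tek (0.4859 against 0.0426 to 0.181) were high. In vector replicate 6, Hes2 was 0.02129 against 0, Grhl3 0.2554 against 0 to 0.0506 and Csf1r 9.835 against 7.53 to 8.34. That Hes2 value is 1 count, the only one in the vector group, so any library holding it would be flagged. In SPARCoe replicate 1, Tek was low (0.2385 against 0.537 to 0.602), and in SPARCoe replicate 3, Gstm1 was high (43.65 against 38.1 to 39.95). In SPARCoe replicate 5, Lamb2 (195.5 against 174.2 to 180.4), Acta2 (57.34 against 51.5 to 52.3), Tln1 (866.8 against 807.5 to 820.3) and Irf7 (164.4 against 155.6 to 158.5) were high. In SPARCoe replicate 6, Ms4a2 was low (0.2688 against 0.871 to 1.12).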

How the results depend on the processing

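Offsets for GC content and gene length were chosen after the data were seen. The number of changed genes ran from 3319 (adjusted p under 0.01) to 5344 (no filter on low counts) over all alternatives but 1 and from 4276 to 4476 with 1 library left out. That 1, glmTreat against 1.2-fold, gave 992. Changes of 2-fold or more numbered 1432 with no filter on low counts, 1107 by DESeq2, 206 with the filter of at least 1 CPM, and 67, 110 and 81 by log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) over all genes. No filter and DESeq2 tested more genes (31742 and 23460) and the filter of at least 1 CPM fewer (12790). For FPKM, lowering the pseudocount from 1 to 0.1 on the same 12421 genes raised the number from 67 to 110. The pseudocount thus accounts for part, and the rest was not tested. The share of rises among them stayed between 95.32% and 98.77%. Of the 24 tested lists, 10 passed, against 7 with an estimated correlation, and 13 of 23 with the filter of at least 1 CPM. By fry 19 passed, but fry tests a list against no change and camera against the other genes. The Sparc log2 fold change ran from 3.74 to 3.765, with no value where Sparc was left out.

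Of 2739 values of the 111 genes that the rule took, 2705 kept direction and side of the threshold, 25 no longer passed (Rpl10, Rpl11, Col4a4, Hsd17b7), 4 newly passed (Col4a3) and 5 changed sign, all of mt-Nd1: -0.002088 with no filter, and -0.01637 (without SPARCoe replicate 4) to 0.03331 (without vector replicate 1) with 1 library left out, the mt-Nd1 log2 fold change being near 0 throughout. With the filter of at least 1 CPM the interstitial matrix, mesangial and cholesterol lists newly passed (adjusted p = 0.0196, 0.0114 and 0.0267). Endothelial markers changed direction with it (camera adjusted p = 0.269). That filter removed Robo4 and Tek, which rose to means of 0.933 and 0.514 CPM in SPARCoe. It kept Eng, which rose, and Flt1, which fell. Leukocyte markers changed direction by fry (adjusted p = 0.566) and without SPARCoe replicate 6 (camera adjusted p = 0.969). With 1 library left out their adjusted p ran from 0.762 to 0.969, and the cause was not tested. Replicate numbers did not pair the libraries: deviations of the same number correlated between -0.011 and 0.015. A block on them gave 4663 changed genes, and Col4a3 and the cholesterol list passed with it (adjusted p = 0.0354 and 0.0408). Depth limits calls at low counts: Nphs1 and Wt1 fell below the filter and were tested by permutation.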

Other observations

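The gene groups in this part were chosen after their values were seen, so their tests are not independent of them. Antigen presentation genes were higher in SPARCoe, 18 of 20 tested members with 0 lower (camera adjusted p = 1.04e-12; adjusted p = 0.025 with an estimated correlation). The list shares 6 genes with the interferon list. Nlrc5, a transactivator of MHC class I genes, rose from 14.3 ± 0.757 to 37.2 ± 1.67 CPM, the peptide transporter gene Tap1 from 20.6 ± 1.19 to 37.7 ± 1.49 CPM and the immunoproteasome gene Psmb8 from 7.04 ± 0.782 to 12.6 ± 0.792 CPM (SD, n = 6). H2 genes have near-identical copies, so their single values are uncertain. Circadian clock genes had 9 of 17 lower and 4 higher (camera adjusted p = 0.134; adjusted p = 0.401 with an estimated correlation). Dbp fell from 4.18 ± 0.574 to 2.19 ± 0.199 CPM and Nr1d1 from 36.9 ± 2.82 to 27.6 ± 1.78 CPM, while Arntl rose from 35.7 ± 0.764 to 43.7 ± 2.99 CPM (SD, n = 6).

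Other single genes with marked changes were the chemokine genes Ppbp (130.8 ± 5.78 to 298.0 ± 9.66 CPM) and Cxcl1 (72.2 ± 6.34 to 261.2 ± 9.48 CPM), the complement gene C3 (10.6 ± 2.72 to 51.0 ± 12.8 CPM) and the envoplakin gene Evpl (2.26 ± 0.364 to 23.96 ± 0.761 CPM; SD, n = 6). Around Trp53 on chromosome 11 (69580359 to 69591873 in GENCODE M21, GRCm38), the neighbours Wrap53, Efnb3 and Dnah2 rose by 0.75, 1.47 and 4.88 on the log2 scale, beside 0.00 ± 0.02 (SE) for Trp53. The 3 genes follow each other on the minus strand, opposite to Trp53, with gaps under 10 kb, and Dnah2 overlaps Dnah2os and Gm27493. Efnb3 and Dnah2 thus have the higher upstream neighbour counted for 8.08% of the 2-fold rises, and their values may include read-through. The interferon gene Ifnb1 rose from 0.06 ± 0.053 to 0.878 ± 0.24 CPM, and Il6 from 0.123 ± 0.0747 to 1.41 ± 0.245 CPM (SD, n = 6).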
